A study of Mus musculus with 27 samples.

How the data were processed

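The samples were snap-frozen prostate tumours of 27 transgene-positive F2 males, from which total RNA was extracted and labelled with biotin using a GeneChip kit, per the labels. There is 1 array per tumour, and with a single label the values were read as those of 1-colour Affymetrix arrays. That the TRAMP transgene is driven by the probasin promoter and that PWK/PhJ is wild-derived is general knowledge and not in the labels. The deposited table holds log2 expression values made by the authors, 41345 rows by 27 arrays between 1.68 and 14.5. Per the submitters' processing notes the tool was Partek; its version, the background correction, the summarisation and the normalization are not given in the sources used here. The array medians were within a narrow range, so the deposited values were used as normalized between arrays, and differences that the authors' normalization removed or added cannot be seen. Arrays hold no read depth, so low values are close to background and the number of arrays limits the precision. All 27 columns matched a sample title.

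Rows were named through the probe table of the array platform: 23521 rows had 1 gene symbol, 1814 had several and 16010 are unnamed here. Rows with several symbols or none were not used for genes. Where a gene had several rows (1082 genes) the row with the highest mean was kept, which gave 22180 genes, and 22139 of their symbols were found in the RefSeq table of the assembly GRCm38.p6; that table served only for names and for which genes neighbour each other on a chromosome. The platform's own build is not given in the sources used here, so no coordinates are given. Of the 236 genes in 23 preset lists, 210 were measured. Krt5 and the red blood cell genes were not named in the probe table and are not analysed here, and the red blood cell list has no value.

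The gene lists, the main tests, most alternatives and the rule for named genes were fixed before the data were examined. Leaving out P425, P219 and P268, leaving out each tumour in turn, the settings with chromosome medians and the tests of single observations were chosen after. The text names, of each list, the 2 members with the largest slope or SD, past the threshold or not. It further names the 10 steepest rising and falling genes per score past the threshold, the 20 genes with the largest SD, the 15 genes with modes of the largest Ashman's D, the genes the study followed up, Xist and the Y-linked genes, and pairs of lists by the size of r. Genes with Rik, Gm, LOC, BC or accession symbols were left out of the rankings by slope and by Ashman's D. Gm1966, Scg3 as an example of the neuroendocrine score, and values of single tumours outside this rule were chosen after their values were seen. The rule allowed 2 to 4 members per list, and 2 was settled on after the slopes were seen.

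A list's score in a tumour was the mean over its measured members of the log2 value minus that gene's mean over the 27 tumours. Separate clusters were called with mclust 6.1.1 when 2 components beat 1 by more than 6 in BIC, Ashman's D was over 2 and the smaller component held at least 3 tumours; correlations and fits were then made within clusters of at least 6 tumours. On simulated data this rule called 0 of 200 single normal groups and 170 of 200 sets of 2 groups lying 5 SD apart. Pearson's r and Spearman's rho were tested two-sided with 100000 permutations, or with all orders below 10 tumours, and adjusted by Benjamini-Hochberg over the 262 relations. Genes were fitted on each score scaled to SD 1 with limma 3.58.1 (lmFit and eBayes with a trend) in R 4.3.3, members of the list were left out, and p was adjusted by Benjamini-Hochberg at a threshold of 0.05. As a test added later, 99 random lists per score, of the same size and matched on mean level in 20 bins, were scored and fitted in the same way. Gene lists were tested with camera at a preset correlation of 0.01 and with an estimated one. The fits were tested on simulated data with the genes' own residual spread and noise drawn independently for each gene: with a slope of 0.5 log2, 90%, 90% and 92% of 100 changed genes were recovered for the neuroendocrine (23 tumours), mitosis and androgen-responsive fits (27 tumours). False calls numbered 8, 4 and 9. Genes on the arrays vary together, so these shares do not describe how stable the real counts are. The labels give no batch; the animal number served as a covariate in an alternative.

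The spread of a list was set against 10000 random lists matched on mean level in 20 bins. Correlations of neighbouring genes used 22126 genes placed on chromosomes, 100000 random pairs from different chromosomes and 1000 shuffled gene orders. Modes per gene were called with mclust (equal variance, 1 to 3 components) at a BIC difference over 10, modes at least 1 log2 unit apart, Ashman's D over 4 and at least 3 tumours per mode; of 200 simulated genes with 3 modes 152 were called. Alternatives covered quantile normalization, centring of each array on its median, a filter at the median level of all rows (5.79 log2, 13041 genes), the mean over probes, z-scored scores, rank correlation, covariates for composition, animal number and mitosis, and leaving out tumours. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1 was used for the remaining steps. Genotypes, tumour weights and metastasis counts are not used here.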

Results

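Gene expression was measured in 27 prostate tumours, each from a different transgene-positive F2 male of a cross between TRAMP mice on C57BL/6 and the wild-derived strain PWK/PhJ. TRAMP mice carry the SV40 early region under the androgen-responsive probasin promoter and develop prostate tumours. The labels say that tumour growth and metastases were scored at 30 weeks or at a humane endpoint, and they place all 27 tumours in 1 group. The arrays therefore show variation among F2 tumours and hold no contrast between conditions. Tumours are named by their animal number, such as P425. The array medians lay between 5.67 and 5.82 on the log2 scale. The correlation between 2 arrays ranged from 0.891 to 0.986 with a median of 0.953, and the closest 2 arrays still differed by a mean of 0.243 log2 per probe set, so no array was counted as a repeat of another. The number of arrays limits the precision.

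Many genes differed widely between tumours. The lowest value of each of the 20 genes with the largest SD lay below the median level of all rows (5.79 log2), where values are close to background, so their folds are lower bounds. Msmb, a secreted prostate protein, ranged over at least 198-fold (SD 2.39 log2, n = 27) and was highest in tumour P219. The membrane peptidase gene Mme ranged over at least 187-fold and was highest in the same tumour. Cdcp3 (131-fold) and Scd1, a fatty acid desaturase gene (122-fold), were highest in P425, Tgm3, a transglutaminase gene (115-fold), in P966, and Scgb2b27 (226-fold) in P502. Among the 20 genes with the largest SD were Cdh1, the gene of E-cadherin (55.6-fold), the desmosome gene Dsp (58.6-fold), Rab25 (62.0-fold), Tmem30b (103-fold) and Slc44a3 (75.7-fold). Also in that set were Pcsk1, a prohormone convertase gene (137-fold), the neuropeptide gene Nmu (95.7-fold), the calcitonin receptor gene Calcr (134-fold), the glycine receptor gene Glra2 (77.3-fold) and Fam171b (61.9-fold). The interferon-induced gene Oas1g ranged over at least 81.3-fold and was highest in P471. The remaining 3 were 2310057J18Rik (at least 484-fold) and 9530002B09Rik (at least 283-fold), both highest in P219, and 2610524H06Rik (at least 187-fold), lowest in P1469. Of 22180 genes, 5617 ranged over more than 4-fold and 1024 over more than 16-fold.

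Preset gene lists differed in how much their members varied. The median SD was 1.53 log2 over the 13 luminal epithelium genes (Cdh1, SD 2.06, and Krt8, 1.97), 1.28 over the 13 androgen-responsive and secretory genes (Msmb, 2.39, and Mme, 2.24) and 1.25 over the 17 neuroendocrine genes (Pcsk1, 2.02, and Stmn2, 1.61). Each lay at percentile 100 of 10000 random lists of the same size matched on mean level. The mitosis list (median SD 0.54; Bub1, 0.74, and Birc5, 0.69), the fibroblast and matrix list (0.82; Dcn, 1.31, and Pdgfra, 1.23), the interferon response list (1.10; Usp18, 1.87, and Oasl2, 1.62) and the hypoxia and glycolysis list (0.80; Egln3, 1.33, and Adm, 1.11) also lay at percentile 100. Percentiles were 99.9 for smooth muscle (Cnn1, SD 1.36, and Des, 1.23) and skeletal muscle (Myh1, 1.30, and Acta1, 1.09), and 99.7 for class I antigen presentation (Tap1, 1.17, and H2-K1, 1.12). They were 99.1 for adipose tissue (Fabp4, 1.50, and Cidec, 0.99) and 98.6 for macrophage and myeloid genes (Adgre1, 0.83, and Cd14, 0.75) and for the Y-linked genes (Uty, 1.19, and Kdm5d, 0.93).

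Lists with a percentile between 95.4 and 96.9 were basal epithelium (Krt17, SD 1.60, and Lamb3, 1.09), seminal vesicle (Svs5, 1.85, and Svs2, 1.49), B and plasma cell (Jchain, 1.67, and Cd79b, 0.78), mesenchymal transition (Zeb1, 0.85, and Cdh2, 0.80) and immediate early genes (Egr1, 1.04, and Atf3, 0.97). The 4 genes the study followed up (Ska3, 0.70, and Gnl3, 0.52) lay at 89.4, T and NK cell genes (Cd3g, 1.08, and Cd3e, 0.47) at 83.2, endothelium (Vwf, 1.40, and Cdh5, 0.88) at 78.5 and DNA replication and E2F targets (Rrm2, 0.75, and Tyms, 0.53) at 63.3. With the median absolute deviation in place of the SD, which is less sensitive to a few tumours, the percentile was 37.0 for skeletal muscle, 53.2 for basal epithelium, 56.9 for T and NK cell genes and 79.8 for adipose tissue, and 62.6 for B and plasma cell genes when genes below the median level were left out. These percentiles describe these arrays.

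The neuroendocrine score, the mean of the centred log2 values of genes such as Pcsk1, Stmn2 and Scg3, was low in 4 tumours. It was -2.45 in P471, -1.77 in P966, -1.65 in P425 and -1.37 in P1276, and lay between -0.23 and 0.79 in the other 23. The luminal epithelium score, built from genes such as Cdh1 and Krt8, was 2.60 in P425, 2.34 in P1276, 2.24 in P966, 1.94 in P219, 1.81 in P569, 1.79 in P471, 1.67 in P1469 and 1.63 in P803. It lay between -1.46 and 0.56 in the remaining 19. The 4 tumours with low neuroendocrine scores were thus among the 8 with high luminal scores. The others of the 8 were P803, with the highest neuroendocrine score (0.79), P1469 (0.66), P569 (0.35) and P219, with the lowest of the 23 (-0.23). Members of the neuroendocrine list differed in P803, P1469 and P569. Pcsk1 was at 12.1, 11.1 and 11.6 log2 there. Stmn2 was at 6.25, 7.06 and 6.81, against 6.73 in P966. Members of the luminal list differed too. Foxa1, 1 of its 13 genes, was lowest in P471 (7.20), P1276 (7.87) and P966 (8.10), and highest in P425 (11.7). Cldn4, another, was at 5.73 in P803 and 5.34 in P1469, against 10.5 in P425. A Gaussian mixture called separate clusters for the neuroendocrine and luminal scores (Ashman's D 8.47 and 6.63). It also called them for the basal epithelium, interferon response, class I antigen presentation and immediate early scores. No pooled correlation is given for those 6 scores and the clusters were not compared. Single tumours stood apart on other scores. The adipose score was 2.92 in P425, the skeletal muscle score 3.06 in P219 and 2.18 in P268, the smooth muscle score 2.19 in P219 and 1.99 in P425, and the B and plasma cell score 1.96 in P471 and 1.32 in P966.

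**Figure D1:**
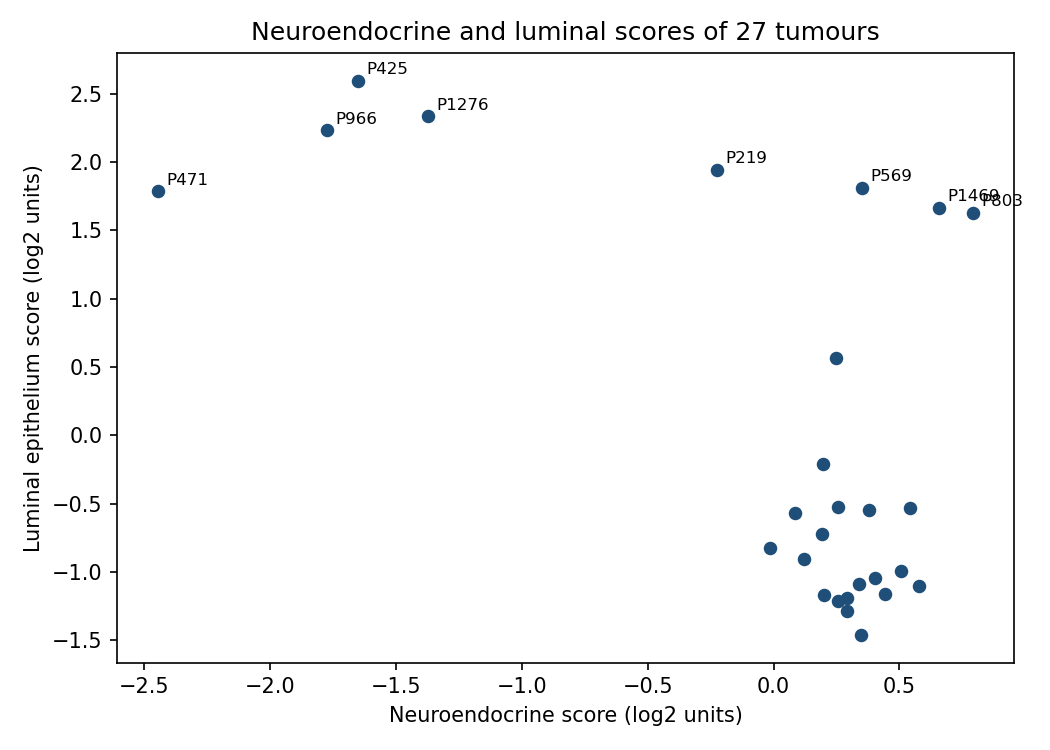
Neuroendocrine score (horizontal axis, log2 units) and luminal epithelium score (vertical axis, log2 units) of the 27 tumours, 1 point per tumour, with the 8 tumours of high luminal score named. P966, P471, P425 and P1276 lie at neuroendocrine scores between -2.45 and -1.37, and P803, P1469 and P569 combine a high luminal score with neuroendocrine scores of 0.79, 0.66 and 0.35.

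Y-linked genes were checked because all animals were male. Eif2s3y was at 8.86 ± 0.86 log2 (SD, n = 27), Kdm5d at 7.82 ± 0.93 and Uty at 8.25 ± 1.19. All 3 were low in P569 (5.86, 4.63 and 5.14) and in P966 (6.96, 5.75 and 6.09), and lower than in most tumours in P1394 (7.64, 6.65 and 7.41). In P1469, Uty was at 4.78 while Eif2s3y was at 8.54 and Kdm5d at 7.04. Xist, the transcript of the inactive X chromosome, lay between 4.01 and 4.96 in all tumours but P569, where it was 5.36.

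**Figure D2:**
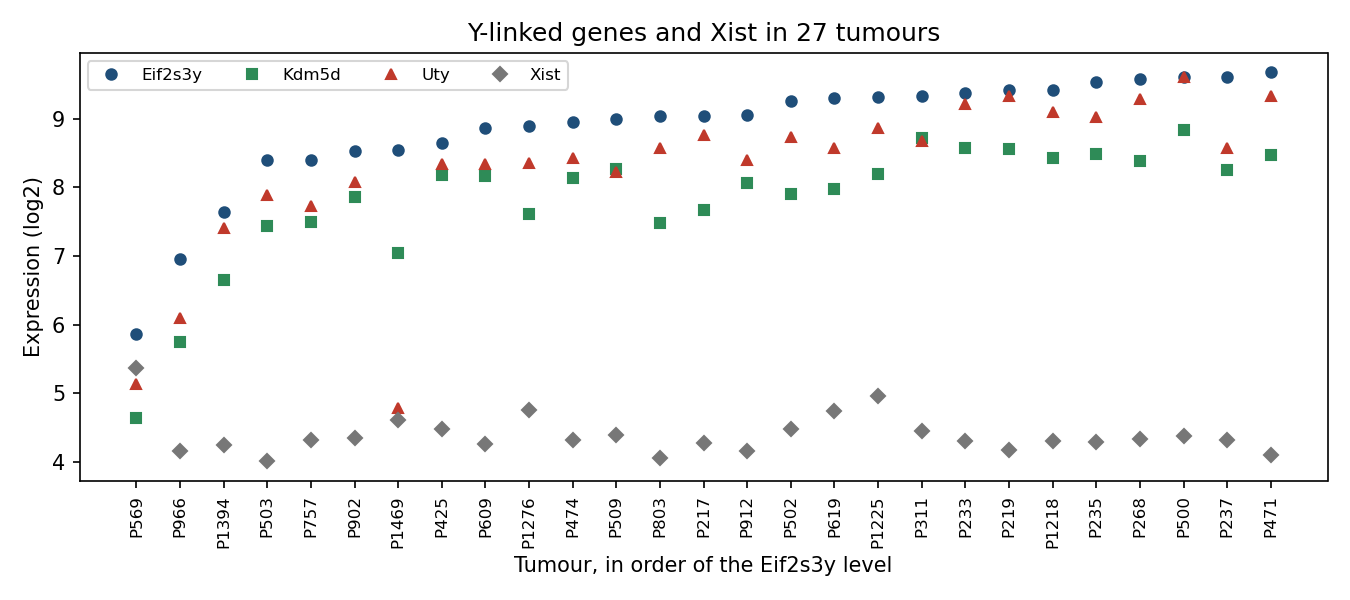
Expression (log2, vertical axis) of the Y-linked genes Eif2s3y, Kdm5d and Uty and of Xist in each of the 27 tumours, in order of the Eif2s3y level; each symbol is 1 tumour's value. P569 and P966 have the lowest Eif2s3y levels, 5.86 and 6.96, and Uty is lowest in P1469 at 4.78.

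Within the 23 tumours with higher neuroendocrine scores, 12 genes followed the score. No call was left without P235, P803 or P1469 or with composition scores as covariates (a count of 0 each), and the count was 644 with z-scored genes and 146 with the mitosis score as a covariate. Scores of random lists did as well: with the real list included, 53 of 100 lists gave at least 12 genes. The synaptic adhesion gene Lrrtm1 rose by 0.64 ± 0.11 log2 (SE) per SD of the score (adjusted p = 0.028), the phosphodiesterase gene Pde10a by 0.45 ± 0.07 (adjusted p = 0.022), and Maneal, Rundc3a, Krtap31-1 and the protein kinase A subunit gene Prkacb by 0.18 to 0.23. Hacd4 fell by 0.61 ± 0.10, Slfn2 by 0.60 ± 0.10, Mertk, a receptor for the uptake of dying cells by macrophages, by 0.53 ± 0.09 (adjusted p = 0.028), Fmn1 by 0.47 ± 0.08, Gm1966 by 0.46 ± 0.09 and Sla by 0.33 ± 0.06. No member of a preset list passed over all genes.

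Adjusted over the list alone, 11 of 12 macrophage and myeloid genes had slopes below 0 that passed, with Mrc1 at -0.47 ± 0.11 and Adgre1 at -0.46 ± 0.13. So did 7 of 8 skeletal muscle genes (Myh1, -0.83 ± 0.23, and Myh4, -0.61 ± 0.20), 6 of 9 smooth muscle genes (Des, -0.62 ± 0.21, and Cnn1, -0.61 ± 0.19), 5 of 13 androgen-responsive genes (Msmb, -1.13 ± 0.40, and Tgm4, -0.71 ± 0.27), 5 of 8 T and NK cell genes (Cd3g, -0.47 ± 0.14, and Cd3e, -0.23 ± 0.07) and 4 of 9 interferon response genes (Oasl2, -0.72 ± 0.25, and Usp18, -0.59 ± 0.23). In the hypoxia and glycolysis list 6 of 11 genes had slopes above 0 that passed adjusted over the list alone (Egln3, 0.61 ± 0.21, and Bnip3, 0.42 ± 0.14). By camera with a preset correlation these 7 lists shifted in those directions, and so did basal epithelium, fibroblast and matrix, class I antigen presentation and adipose genes downward. With an estimated correlation none of them passed. The macrophage list had adjusted p = 0.078, the skeletal muscle, smooth muscle, androgen-responsive and T and NK cell lists adjusted p = 0.2, the interferon, antigen presentation and basal lists adjusted p = 0.26, the hypoxia and adipose lists adjusted p = 0.28 and the fibroblast list adjusted p = 0.37. Several of these relations were weaker without P219 and P803, the 2 tumours farthest on the score. Without them the correlation of the neuroendocrine score with the smooth muscle score went from r = -0.542 (rho = -0.249) to -0.213. With the androgen-responsive score it went from -0.461 (rho = -0.118) to -0.110, with T and NK cell genes from -0.535 (rho = -0.241) to -0.304, and with skeletal muscle from -0.545 (rho = -0.328) to -0.369. None of these passed the adjustment, and the hypoxia score went from 0.482 to 0.391. The interferon slopes pool both clusters of the interferon score. Within the 19 tumours of its lower cluster the sign was the opposite, with r = 0.521 (rho = 0.446, adjusted p = 0.14 and 0.21) and 0.265 without the 2 farthest of the 19. Class I antigen presentation had r = 0.220 within the 20 tumours of its lower cluster (adjusted p = 0.61).

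The largest slopes in the lists with no member past either adjustment were those of Cldn4 (-0.52 ± 0.17) and Krt8 (0.36 ± 0.33) in luminal epithelium, Krt15 (-0.34 ± 0.14) and Pdpn (-0.32 ± 0.11) in basal epithelium, Svs5 (-0.68 ± 0.38) and Svs4 (-0.37 ± 0.19) in the seminal vesicle list, and Pdgfra (-0.59 ± 0.22) and Dcn (-0.50 ± 0.24) in the fibroblast list. They were Vwf (0.60 ± 0.28) and Emcn (-0.23 ± 0.13) in endothelium, Jchain (-0.43 ± 0.25) and Mzb1 (0.17 ± 0.08) among B and plasma cell genes, H2-K1 (-0.36 ± 0.17) and Tap1 (-0.35 ± 0.16) in antigen presentation, and Fabp4 (-0.42 ± 0.26) and Cidec (-0.26 ± 0.12) in adipose tissue. Mitosis (Aurkb, 0.11 ± 0.06, and Ccnb2, 0.10 ± 0.08), DNA replication (Gins1, -0.15 ± 0.08, and E2f1, 0.12 ± 0.07), mesenchymal (Prrx1, -0.21 ± 0.10, and Vim, -0.15 ± 0.10) and immediate early genes (Fos, 0.13 ± 0.11, and Ier2, 0.08 ± 0.07) had smaller slopes. In 3 of these lists the camera test pointed down while the median slope was above zero. Luminal genes had a median slope of 0.09 and a mean of 0.07 (adjusted p = 0.78). DNA replication genes had 0.01 and -0.01 (adjusted p = 0.43). Mesenchymal genes had 0.02 and -0.03 (adjusted p = 0.63).

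In all, 12 of 22163 genes passed in that fit, 6 rising and 6 falling (limma, adjusted p under 0.05), against 3394 at an unadjusted p under 0.05. The count was 0 without P235, P803 or P1469, 7 without P502 or P268, 19 without P217, 31 without P233 and 33 without P509. It was also 0 with fibroblast, smooth muscle, macrophage and endothelium scores as covariates, 175 after quantile normalization (106 rising and 69 falling) and 85 with each array centred on its median (61 rising and 24 falling).

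Many genes rose or fell along the mitosis score. The steepest genes were ranked without the list's own members and without Rik, Gm, LOC, BC or accession symbols. Genes with the steepest rise were Nmu (1.05 ± 0.34 log2 per SD, SE, n = 27, adjusted p = 0.024), the neural adhesion gene Cntn1 (1.03 ± 0.30), the glutamate receptor gene Gria2 (1.01 ± 0.25), the thyrotropin-releasing hormone receptor gene Trhr (0.99 ± 0.30), the secretogranin gene Scg3 (0.98 ± 0.23, adjusted p = 0.0022), Eya4 (0.98 ± 0.23), Asb4 (0.97 ± 0.31), Nexmif (0.96 ± 0.19) and the potassium channel gene Kcnmb2 (0.92 ± 0.23). Snhg14 lay between Gria2 and Trhr in this order (adjusted p = 0.002). Genes with the steepest fall were Rab25 (-1.34 ± 0.32, adjusted p = 0.0028), Dsp (-1.34 ± 0.34), Cdh1 (-1.31 ± 0.30), Slc44a3 (-1.27 ± 0.30) and the serine protease gene Tmprss2 (-1.25 ± 0.25). They were followed by Pate9 (-1.24 ± 0.29), the serine protease gene St14 (-1.24 ± 0.30), the keratin gene Krt8 (-1.23 ± 0.29), Perp (-1.21 ± 0.25) and the epithelial splicing factor gene Esrp1 (-1.14 ± 0.30).

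Of the preset lists, 11 of 15 DNA replication and E2F target genes rose with the mitosis score (12 adjusted over the list alone), led by Rrm2 (0.59 ± 0.09) and Tyms (0.47 ± 0.05). This list passed camera with an estimated correlation too (adjusted p = 0.008). Among neuroendocrine genes 6 of 17 rose (7 adjusted over the list alone), with Scg3 (0.98 ± 0.23) and Scg5 (0.73 ± 0.19) first, and adjusted p = 0.6 with an estimated correlation. Of the luminal epithelium genes 11 of 13 fell (11 adjusted over the list alone), Cdh1 and Krt8 most, with adjusted p = 0.44 with an estimated correlation. Of the androgen-responsive genes 9 of 13 fell (11 adjusted over the list alone), with Tmprss2 (-1.25 ± 0.25) and Spink1 (-1.10 ± 0.18) first and adjusted p = 0.22 with an estimated correlation. The 2 scores had r = -0.705, and 0.080 without P425 and P219. Of smooth muscle genes 7 of 9 fell (8 adjusted over the list alone; Cnn1, -0.88 ± 0.20, and Myh11, -0.59 ± 0.17), with adjusted p = 0.49 with an estimated correlation. Of adipose genes 5 of 6 fell (6 adjusted over the list alone; Cidec, -0.70 ± 0.13, and Plin1, -0.64 ± 0.09), with adjusted p = 0.24 with an estimated correlation. In class I antigen presentation 3 of 8 genes fell (3 adjusted over the list alone; H2-K1, -0.55 ± 0.18, and Tapbp, -0.50 ± 0.12), with adjusted p = 0.81 with an estimated correlation. These slopes over 27 tumours pool the clusters of the neuroendocrine, luminal and antigen presentation scores, and no relation within those clusters passed the adjustment. The neuroendocrine and mitosis scores had r = -0.098 within 23 tumours (adjusted p = 0.82). The luminal and mitosis scores had r = 0.247 within the 19 tumours of lower luminal score (adjusted p = 0.57). Within the 8 of higher luminal score r was -0.720 (adjusted p = 0.16), and -0.057 without the 2 farthest. Antigen presentation had r = -0.022 within 20 tumours and -0.263 within 7. Without P425 and P803 r with the smooth muscle score went from -0.599 to -0.375 and with the adipose score from -0.697 to -0.223.

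The mesenchymal genes Cdh2 (0.56 ± 0.11) and Zeb1 (0.43 ± 0.14) rose (2 adjusted over the list alone), the other 6 of that list did not pass, and its median slope (-0.01) differed in sign from its mean slope (0.08) and from the upward camera test (adjusted p = 0.59). Basal epithelium had 2 of 7 genes that fell (2 adjusted over the list alone), and its largest slopes, those of Krt17 (-0.56 ± 0.28) and Lamb3 (-0.34 ± 0.20), did not pass. In the seminal vesicle list 2 of 7 fell (2 adjusted over the list alone), Svs3b (-0.18 ± 0.06) among them, while Svs5 (-0.15 ± 0.35) did not pass. A single gene fell in the hypoxia list (Hk2, -0.61 ± 0.17; 1 adjusted over the list alone), among T and NK cell genes (Gzmb, -0.19 ± 0.06; 1 adjusted over the list alone), in the interferon list (Irf7, -0.56 ± 0.20; 0 adjusted over the list alone) and in endothelium (Cldn5, -0.19 ± 0.07; 0 adjusted over the list alone). The other members of these lists with large slopes, Slc2a1 (-0.42 ± 0.18), Cd3e (-0.13 ± 0.09), Usp18 (-0.66 ± 0.33) and Vwf (-0.46 ± 0.25), did not pass. No gene passed among fibroblast (Dcn, -0.26 ± 0.24, and Lum, -0.18 ± 0.17), macrophage (Cd68, 0.20 ± 0.10, and Cd14, -0.19 ± 0.14), B and plasma cell (Jchain, -0.27 ± 0.31, and Cd79a, -0.08 ± 0.11), immediate early (Atf3, -0.38 ± 0.17, and Junb, -0.29 ± 0.11) and skeletal muscle genes (Acta1, -0.30 ± 0.20, and Ckm, -0.15 ± 0.14). The basal, interferon and immediate early slopes pool both clusters of those scores. Within clusters no relation of the basal or interferon score with the mitosis score passed the adjustment. Within the 19 tumours of lower immediate early score the mitosis and immediate early scores had r = -0.707 (permutation p adjusted to 0.0099).

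Over all genes 6019 of 22165 followed the mitosis score (2897 rising and 3122 falling, limma, adjusted p under 0.05). Such a count is not particular to this list, since 29 of 100 lists, the real one and random ones of the same size and mean level, gave as many. P425 had a mitosis score of -1.90 and the other 26 tumours lay between -0.40 and 0.51, and without P425 and P803 the count was 3661. With P425, P219 and P268 left out, Pate9 (0.11), Cidec (0.06) and Gzmb (0.02) had slopes above 0, none of them past the threshold.

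Smooth muscle and adipose genes rose with the androgen-responsive and secretory prostate score. Among genes outside the androgen-responsive list, without Rik, Gm, LOC, BC or accession symbols, the steepest were Cdcp3 (1.96 ± 0.29 log2 per SD, SE, n = 27, adjusted p = 2.3e-05), Scgb2b27 (1.82 ± 0.22), Pate9 (1.78 ± 0.16) and the cytochrome gene Cyp2f2 (1.72 ± 0.13). Ceacam1 (adjusted p = 3.8e-08), Tcaf3 (1.60 ± 0.14), the matrix protease gene Mmp7 (1.53 ± 0.22), the uroplakin gene Upk1b (1.53 ± 0.11), Papss2 (1.53 ± 0.16) and Timp4 (1.48 ± 0.11) came next. The steepest falls were in Rgs16 (-0.79 ± 0.13, adjusted p = 9.5e-05), the somatostatin receptor gene Sstr2 (-0.75 ± 0.25), Sema3e (-0.73 ± 0.17), Dner (-0.65 ± 0.16) and Dclk2 (-0.58 ± 0.15). Rtkn2 (-0.58 ± 0.10), the mitotic kinesin gene Kif18a (-0.58 ± 0.11), Ak4 (-0.57 ± 0.13), Dusp4 (-0.56 ± 0.14) and Mtmr7 (-0.56 ± 0.15) followed. P425 (score 3.73) and P219 (2.13) had the highest scores, and the same tumours had the highest smooth muscle and adipose scores.

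By list, 8 of 9 smooth muscle genes rose with that score (8 adjusted over the list alone; Cnn1, 1.16 ± 0.14, and Des, 0.96 ± 0.15) and all 6 adipose genes (6 adjusted over the list alone; Fabp4, 1.04 ± 0.21, and Cidec, 0.87 ± 0.09). Both lists passed camera with an estimated correlation (adjusted p = 0.013 and adjusted p = 0.0066). Their correlations with the score were weaker without P425 and P219. For smooth muscle r went from 0.852 to 0.549 and for adipose from 0.878 to 0.492. Of the DNA replication genes 8 of 15 fell (12 adjusted over the list alone; adjusted p = 0.043 with an estimated correlation); Rrm2, with the largest slope (-0.35 ± 0.13), did not pass over all genes and Tyms (-0.31 ± 0.08) did. The DNA replication relation too rested on P425 and P219: without them r went from -0.744 to -0.044 and the slope of Tyms was 0.03. Of the mitosis genes 14 of 15 fell (15 adjusted over the list alone; Bub1, -0.49 ± 0.11, and Birc5, -0.41 ± 0.11), with adjusted p = 0.08 with an estimated correlation. The androgen-responsive and mitosis scores had r = -0.705 over 27 tumours (rho = -0.277, adjusted p = 0.071 and 0.39) and r = 0.080 without P425 and P219, on which this relation rested. Rising genes were 6 of 13 in luminal epithelium (7 adjusted over the list alone; Cldn4, 1.06 ± 0.30, and Cdh1, 1.05 ± 0.34) and 4 of 9 in the interferon response (7 adjusted over the list alone; Oasl2, 1.08 ± 0.23, and Usp18, 0.93 ± 0.31). In skeletal muscle 4 of 8 rose (7 adjusted over the list alone; Acta1, 0.73 ± 0.16, and Myh1, 0.64 ± 0.21), and in class I antigen presentation 6 of 8 (7 adjusted over the list alone), H2-K1 by 0.75 ± 0.16, while Tap1 (0.57 ± 0.19) did not pass over all genes. In basal epithelium 1 of 7 genes rose, Krt15 (0.55 ± 0.10), and 3 passed adjusted over the list alone, Krt14 (0.22 ± 0.08) among them. Each of these 5 lists had adjusted p = 0.26 with an estimated correlation. The luminal, interferon, antigen presentation and basal slopes pool the clusters of those scores. With the interferon score r was 0.257 within 19 tumours and -0.103 within 8, with antigen presentation 0.557 within 20 and -0.005 within 7, and with the basal score 0.476 within 19 and 0.048 within 8. None of these passed the adjustment. With the luminal score r was 0.748 within 19 tumours, which passed (adjusted p = 0.01), and 0.382 without the 2 farthest. Within the other 8 it was 0.639 (adjusted p = 0.23).

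Among T and NK cell genes 3 of 8 rose (3 adjusted over the list alone), Cd3e by 0.26 ± 0.08, while Cd3g (0.42 ± 0.19) did not pass, with adjusted p = 0.29 with an estimated correlation. In the hypoxia list Vegfa (-0.41 ± 0.10) was the 1 of 11 genes that fell (2 adjusted over the list alone), Egln3 (-0.53 ± 0.23) did not pass, and adjusted p = 0.49 with an estimated correlation. The neuroendocrine list shifted down by camera with a preset correlation (adjusted p = 0.0073) and had adjusted p = 0.49 with an estimated correlation; 0 of its 17 genes passed, with Scg3 at -0.55 ± 0.28 and Celsr3 at -0.49 ± 0.21. The mesenchymal gene Cdh2 fell by 0.46 ± 0.13 (1 adjusted over the list alone) and Prrx1 (0.26 ± 0.11) did not pass; the mean slope of that list (-0.02) differed in sign from its median slope (0.03) and from the upward camera test (adjusted p = 0.97). A single gene rose in each of 3 lists (1 adjusted over the list alone in each): Dcn by 0.67 ± 0.21 in the fibroblast list, with Postn at 0.32 ± 0.19, Cldn5 by 0.20 ± 0.06 in endothelium, with Tek at 0.24 ± 0.10, and 1 seminal vesicle gene, not among the largest slopes of Svs5 (0.59 ± 0.33) and Svs2 (0.26 ± 0.28). No gene passed among macrophage (Mrc1, 0.20 ± 0.14, and Adgre1, 0.17 ± 0.16), B and plasma cell (Jchain, 0.27 ± 0.31, and Pax5, -0.15 ± 0.09) and immediate early genes (Egr1, 0.21 ± 0.19, and Jun, -0.12 ± 0.11).

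The androgen-responsive fit called 2626 of 22167 genes (1460 rising and 1166 falling, limma, adjusted p under 0.05), and the number rested on a few tumours: it was 533 without P425, 58 without P425 and P219, and 36 without P425, P219 and P268. It was 167 with fibroblast, smooth muscle, macrophage and endothelium scores as covariates, where Myh1 (-0.29) had a slope below 0. The smooth muscle score is itself correlated with the fitted score (r = 0.852), which lowers the count. With the mitosis score as a covariate it was 1403. Of 100 lists, the real one and random ones, 41 gave at least 2626 genes.

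**Figure D3:**
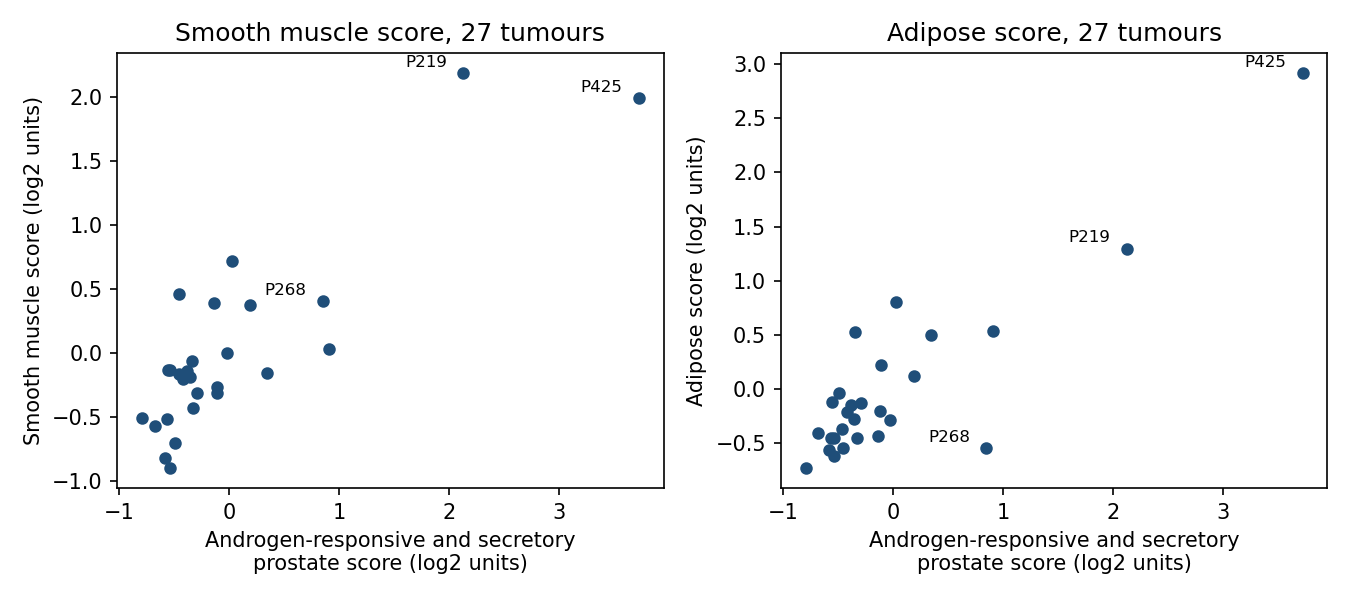
Smooth muscle score (left) and adipose score (right), both in log2 units, against the androgen-responsive and secretory prostate score (log2 units) of the 27 tumours, 1 point per tumour. P425, at an androgen-responsive score of 3.73, has a smooth muscle score of 1.99 and an adipose score of 2.92.

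Some pairs of list scores were correlated between tumours. The fibroblast and matrix score (Dcn, Pdgfra) correlated with the macrophage score (Adgre1, Cd14) at r = 0.762 (rho = 0.684, n = 27, permutation p adjusted to 0.00087 for r and 0.01 for rho) and with the endothelium score (Vwf, Cdh5) at r = 0.715 (rho = 0.702, adjusted p = 0.0022 and 0.01). Without the 2 tumours farthest on the fibroblast score r was 0.658 and 0.652. The mitosis score correlated with the DNA replication score at r = 0.894 (rho = 0.614, adjusted p = 0.00087 and 0.025), and at r = 0.639 without the 2 farthest tumours. Within the 19 tumours of lower immediate early score, mitosis and immediate early genes (Egr1, Atf3) had r = -0.707 (rho = -0.789, adjusted p = 0.0099 and 0.01), and r = -0.728 without the 2 farthest. The androgen-responsive score correlated with the smooth muscle score at r = 0.852 (rho = 0.690, adjusted p = 0.00087 and 0.01) and with the adipose score at r = 0.878 (rho = 0.658, adjusted p = 0.001 and 0.011). Without the 2 farthest tumours r was 0.549 and 0.492. Its r of -0.744 with DNA replication (rho = -0.311, adjusted p = 0.026 and 0.31) rested on P425 and P219, since r was -0.044 without them. Within the 19 tumours of lower luminal score its r with the luminal score was 0.748 (rho = 0.682, adjusted p = 0.01 and 0.033), and this relation rested on the 2 farthest tumours, since r was 0.382 without them.

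Within the 23 tumours of higher neuroendocrine score, the neuroendocrine and macrophage scores had r = -0.688 (rho = -0.501, permutation p adjusted to 0.0099 and 0.099), and r = -0.510 without the 2 farthest tumours. Class I antigen presentation (Tap1, H2-K1) rose with T and NK cell genes (Cd3g, Cd3e) within 20 tumours (r = 0.738, rho = 0.723, adjusted p = 0.0045 and 0.016), with the interferon score within 19 (r = 0.726, rho = 0.651, adjusted p = 0.0099 and 0.048) and with the luminal score within 17 (r = 0.771, rho = 0.652, adjusted p = 0.0045 and 0.064). Without the 2 farthest tumours these r were 0.643, 0.640 and 0.595. Cd3g (mean 5.05 log2) and Cd3e (5.55) lay below the median level of all rows (5.79), where values are close to background. Too few T and NK cell genes lay at or above that level to repeat the relation without the dim genes. Basal epithelium and smooth muscle had r = 0.832 within 19 tumours (rho = 0.732, adjusted p = 0.001 and 0.016) and r = 0.809 without the 2 farthest. Of the 7 basal genes, Krt14 (mean 5.29 log2 over 27 tumours), Krt15 (4.13) and Trp63 (5.39) lay below 5.79 and Col17a1 (5.95) close to it. Pdpn had the highest mean (7.04). The basal score within these 19 tumours thus rests in part on dim genes. Smooth muscle and adipose scores had r = 0.770 over 27 tumours (rho = 0.485, adjusted p = 0.0045 and 0.099), a relation that rested on the 2 farthest tumours, since r was 0.388 without them. The other 3 of the 10 largest correlations outside the 3 main scores came from 8 tumours each and did not pass the adjustment. By exact permutation tests, B and plasma cell and interferon scores had r = 0.857 (rho = 0.833, adjusted p = 0.053 and 0.099), fibroblast and immediate early scores r = 0.849 (rho = 0.786, adjusted p = 0.099 and 0.15), and basal epithelium and endothelium r = 0.786 (rho = 0.667, adjusted p = 0.14 and 0.26). Without the 2 farthest tumours these r were 0.748, 0.720 and 0.853. In total 262 relations of 190 pairs of lists were computed, of which 25 passed the adjustment (19 positive and 6 negative). Of the 25, 14 passed by both r and rho, and 18 kept their sign without the 2 farthest tumours with a p under 0.05 that was not adjusted. Adjusted again over all relations without those tumours, 10 passed. Of the relations with the neuroendocrine, mitosis and androgen-responsive scores, 1 of 19, 2 of 24 and 4 of 24 passed.

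The study is known to have followed up Gnl3, Ska3, Mat1a and Zmym5, which it chose on these samples together with metastasis data not used here, so they are not independent evidence. Ska3, which helps attach chromosomes to the spindle, was at 8.50 ± 0.70 log2 (SD, n = 27) and rose by 0.63 ± 0.06 (SE) per SD of the mitosis score (adjusted p = 1.6e-08). Gnl3, the gene of nucleostemin, was at 8.27 ± 0.52 and rose by 0.32 ± 0.08 (adjusted p = 0.0038), and Zmym5 was at 9.66 ± 0.34 and rose by 0.21 ± 0.05 (adjusted p = 0.0034). Mat1a, a methionine adenosyltransferase gene, ranged from 4.38 to 6.65 and had a slope of -0.21 ± 0.08 (adjusted p = 0.064). Adjusted over the list alone 4 of 4 passed, which is not independent evidence, and the list had adjusted p = 0.19 with an estimated correlation. On the neuroendocrine score within 23 tumours none of the 4 passed over all genes, with slopes of -0.16 for Gnl3, -0.17 for Ska3, 0.20 for Mat1a and -0.17 for Zmym5. Adjusted over the list alone 1 of 4 passed there. On the androgen-responsive score Ska3 fell by 0.39 ± 0.11 (adjusted p = 0.024), with slopes of 0.05 without the 2 farthest tumours and 0.12 with the mitosis score as a covariate. Tumour P803 had the lowest Gnl3 (6.84) and Zmym5 (8.81) levels and the highest Mat1a level (6.65), and P425 had the lowest Ska3 level (6.08).

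Neighbouring genes were compared because F2 animals inherit long stretches of either grandparental genome. Over 19074 adjacent gene pairs, with pairs of the same symbol stem left out, the mean r between tumours was 0.131, against 0.013 for pairs on different chromosomes, an excess of 0.118. The largest excess in 1000 shuffled gene orders was 0.0082 (two-sided permutation p = 0.001, the smallest that these permutations can give). The excess was 0.042 at 5 genes apart and 0.022 at 50 genes apart. After removal of the first 5 principal components it was 0.111 for adjacent genes and 0.029 at 50 apart. These are correlations averaged over genes, which are not independent replicates. Shuffled gene orders show that the order of genes matters and do not show why. Genotypes were not used, so inheritance as the source of the excess was not tested.

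**Figure D4:**
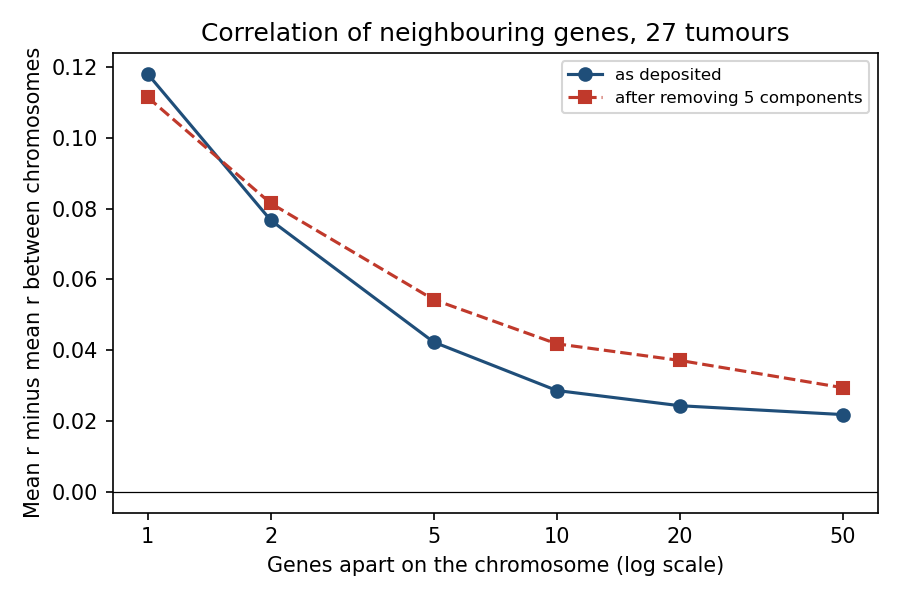
Mean correlation between tumours of 2 genes on a chromosome minus that of genes on different chromosomes (vertical axis, Pearson's r) against the number of genes apart (horizontal axis, log scale), for 27 tumours. Circles are the deposited values, falling from 0.118 for adjacent genes to 0.022 at 50 genes apart, and squares are the values after removal of 5 principal components.

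Genes with separate levels in different tumours were mostly shared by a few tumours. Wnt7a, Pax3, Gpa33, Akp3, Grhl3, Prkcq and S100a14 were high in P471, P966 and P1276 alone; the homeobox gene Pax3 lay between 8.09 and 8.69 log2 there and between 4.78 and 5.47 in the other 24 tumours. Pkd1l3, Cryba2 and Clca3b were high in P569, P803 and P1469 alone, with the modes of Pkd1l3 4.42 log2 apart. Hoxb3 was high in P500, P569, P609 and P803, Ahsg in P471, P569, P966, P1276 and P1469, Foxl2os in P219, P474 and P609, and Prol1 in P219, P235 and P268 (8.16 to 9.96 against 2.86 to 4.58). Rtn1, a reticulon gene, was low in P425, P471, P966 and P1276 (6.48 to 7.29 against 8.97 to 9.93). In all 1003 genes had separate modes, 988 with 2 and 15 with 3, against 3 in normal data and 6 in resampled data of the same size. The smaller mode held exactly P425, P471, P966 and P1276 for 169 genes and P471, P966 and P1276 for 129, and it held 11 or more tumours for 10 of the 988 genes. With a BIC difference over 20 the count was 389 and with modes at least 2 log2 units apart it was 603.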

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

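Leaving out P425, P219 and P268, leaving out each tumour in turn, and subtracting or adjusting for chromosome medians were chosen after the results were seen; the other alternatives were fixed before the data were examined. The excess correlation of neighbouring genes (0.107 to 0.154) kept its direction and side of the threshold under each alternative run. Of 22 lists, 13 had a spread in the top 2.5% of random lists, 9 by the median absolute deviation (smooth muscle, skeletal muscle, adipose and Y-linked genes fell under it), 13 after quantile normalization and 11 without genes below the median level.

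The count of genes related to the neuroendocrine score (12) was 175 with quantile normalization, 85 with each array centred on its median, 30 with only genes at or above the median level, 644 with z-scored genes, 146 with the mitosis score as a covariate, 2 with the animal number as a covariate, 1 by Spearman correlation, 1 without P425, P219 and P268 (P425 is not in this fit), and 0 with composition scores as covariates or without the 2 farthest tumours; leaving out each tumour in turn gave 0 to 33. For the mitosis score (6019) the count was 3661 without the 2 farthest tumours and 4281 to 6483 with each tumour left out. For the androgen-responsive score (2626) it was 167 with composition scores, 58 without the 2 farthest tumours, 543 by Spearman correlation, 1403 with the mitosis score as a covariate, 36 without P425, P219 and P268, and 533 to 3176 with each tumour left out. The correlations between lists that passed (25) numbered 10 without the 2 farthest tumours and 13 with only members at or above the median level. Genes with modes (1003) numbered 389 with a BIC difference over 20 and 603 with modes 2 log2 units apart. The cause was not tested, except that settings without tumours fit fewer of them and the stricter mode rules call fewer genes by construction.

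Changes of sign were counted here only where the main setting or the alternative passed. A change of sign where neither passed was counted as a kept call. Of 1881 slopes of 179 named genes under alternatives, 1581 kept their call, 49 newly passed, 16 changed sign and the rest no longer passed. Of 580 correlations of 74 named relations, 550 kept their call, 18 no longer passed, 11 newly passed and 1 changed sign. On the mitosis score, Pate9 (0.106), Cidec (0.057) and Gzmb (0.0159) changed sign without P425, P219 and P268, and Myh11 (0.0585) with composition scores. On the androgen-responsive score, Des (-0.124) and Myh1 (-0.288) did so with composition scores, and Bub1 (0.0208), Birc5 (0.0714), Tyms (0.0521), Ska3 (0.123) and Zmym5 (0.234, adjusted p = 0.019) with the mitosis score as a covariate. Bub1 and Birc5 are members of the list whose mean is that covariate, as Des and Myh11 are of the smooth muscle list among the composition scores, so their change of sign there says nothing about their slopes in the main fit. Without the 2 farthest tumours Birc5 (0.0605), Tyms (0.0291) and Ska3 (0.0463) did so. Without P425, P219 and P268 Birc5 (0.0322) and Tyms (0.0172) did, and r of the androgen-responsive and DNA replication scores was 0.019. The cause was not tested. Low array values lie near background, and no measure of background was used.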

Other observations

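The tests in this part were chosen after the patterns were seen, among them the bound of 0.2 log2 for chromosome medians, the bound of 1 log2 for Y-linked genes and the use of an interval in the comparison of the 2 ends of each chromosome. The comparison itself and its shares, and the bounds for random lists, were written before their results were known.

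The median over the genes of a chromosome was shifted in single tumours, in some over 1 end only. Relative to the median tumour, the 752 genes of chromosome 1 at or above the median level had a median shift of 0.32 log2 in P235, 0.30 in P1218 and 0.22 in P1394. The median over chromosome 18 was 0.33 in P471 and 0.30 in P1276, over chromosome 6 it was 0.27 in P233 and 0.22 in P569, over chromosome 8 it was 0.26 in P311, and over chromosome 10 it was 0.25 in P1218. The median over chromosome 14 was -0.46 in P803, where 81.7% of its 453 genes lay below their median tumour, and -0.24 in P912. Chromosome 19 fell into clusters of 15 and 12 tumours (Ashman's D 5.49), with medians up to 0.02 in the first and from 0.09 in the second: P500 (0.33), P425 (0.31), P966 (0.30) and P1276 (0.27) were the highest and P1394 (-0.25), P1218 (-0.23) and P503 (-0.21) the lowest. The X chromosome was at -0.24 in P425, -0.23 in P1276 and -0.205 in P966. These 3 are among the 4 tumours of low neuroendocrine score, and other differences of those tumours were not separated from these shifts. In P502 the X chromosome was at 0.27, with 0.05 over the first part of its genes and 0.43 over the last. Chromosome 8 in P569 likewise had 0.01 over the first part and 0.28 over the last. Gnl3, Ska3, Zmym5 and Mat1a all lie on chromosome 14 in GRCm38.p6. With the chromosome 14 median as a covariate in limma their slopes on the mitosis score were 0.23 for Gnl3 (adjusted p = 0.012), 0.56 for Ska3 (adjusted p = 4.3e-09), 0.15 for Zmym5 (adjusted p = 0.0081) and -0.12 for Mat1a (adjusted p = 0.25). In the same fit all of them had slopes on the chromosome 14 median that passed, Mat1a in the opposite direction. The slopes per SD of that median were 0.29 for Gnl3 (adjusted p = 0.018), 0.23 for Ska3 (adjusted p = 0.011), 0.21 for Zmym5 (adjusted p = 0.0052) and -0.29 for Mat1a (adjusted p = 0.03). Outside P803 and P912 that median lay between -0.07 and 0.07, so P803 weighs heavily in these slopes. P803 also had the lowest Gnl3 (6.84) and Zmym5 (8.81) levels and the highest Mat1a level (6.65). Mat1a was high in P569 too (6.145), where the median was -0.07. Whether the slopes hold without P803 was not tested.

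Of 540 tumour and chromosome medians, 33 lay beyond 0.2 log2, and none did in any of 1000 shufflings of genes among chromosomes (largest shift 0.173). Chance over genes that vary independently was thus excluded as the source of these shifts. Neighbouring genes are correlated and shuffling breaks this, so chance over correlated genes was not tested. An array-wide offset was not tested either, since each tumour was centred on its median over all genes beforehand. Gained or lost copies of whole chromosomes are a candidate explanation, as a hypothesis. The largest upward shift from the median tumour, 0.334, lies under the 0.585 that 3 copies in place of 2 would give. Only a shift above that bound could have counted against copy number, and a smaller one does not favour it. Where the first part of a chromosome (by gene order, 1 of 3) was shifted beyond 0.2, the last part kept a median of 76.5% of that shift (bootstrap 95% interval 62.2 to 94.7, 28 cases, the same sign in 26), and a share over 75% had been set for copy number and under 50% for inherited alleles or mismatched probes, which travel in recombining segments. From the last part to the first, a direction added later, the median was 70.4% (interval 60.5 to 84.3, 42 cases, the same sign in 41). Shifts of 1 end only, as on X in P502 and on chromosome 8 in P569, are not those of a whole chromosome. Both intervals lay above the 50% set for inherited alleles, so that prediction was not met, and both spanned the 75% set for copy number. Of the 28 cases 17 lay outside chromosome 19 (median 75.5%, the same sign in 15). The intervals treat all cases as independent, although many share a chromosome or a tumour. This test therefore does not settle between copy number and inherited alleles, and genotypes were not used here. After each tumour's chromosome median was subtracted the excess correlation of neighbours was 0.107 for adjacent genes and 0.015 at 50 genes apart.

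The low levels of Eif2s3y, Kdm5d and Uty in P569 and P966 may reflect loss of the Y chromosome in tumour cells, a hypothesis that was not tested directly. A variant under the probes of 1 gene is excluded as the whole source, since all 3 genes lay more than 1 log2 below the median of the other 25 tumours in both. RNA of a female is argued against in P966, where Xist was 4.158, inside the range of the other 25 tumours (4.01 to 4.96). In P569 Xist was 5.361, above that range but below the median level of all rows (5.79), and no female sample gives a reference level. A female sample in place of P569 is excluded: 3 of the 7 seminal vesicle genes, Svs2 (9.10), Svs4 (6.08) and Svs5 (11.3), lay above both that level and the median of the other tumours. A mixture with some female RNA and loss of the Y chromosome cannot be told apart there.

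The genes that rose with the androgen-responsive score may come in part from host gland, stroma or fat in the samples of P425 and P219. The count of rising genes fell from 1460 to 135 with fibroblast, smooth muscle, macrophage and endothelium scores as covariates. This test decides nothing, since the smooth muscle score is itself correlated with the fitted score (r = 0.852) and such a covariate lowers the count in any case. P425 had the highest levels of Cidec (9.94), Plin1 (9.43) and Scd1 (11.7). P219 also had high skeletal muscle genes (score 3.06; Myh1 9.28 and Ckm 8.70), which gland or stroma of a tumour would not be expected to give and which suggest host muscle in that sample, while the score was -0.04 in P425. For the gland, smooth muscle and fat genes, a tumour with more glandular differentiation and more stroma of its own stays open, and no biological explanation was tested.

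A chance assignment of scores to tumours can be excluded as the source of the counts of genes that followed the scores. Among 100 assignments the real one had the highest count for each score, with 12 genes against a highest other count of 1 for the neuroendocrine score, 6019 against 1630 for the mitosis score and 2626 against 1660 for the androgen-responsive score. The median of the other counts was 0, 2 and 1. This does not make the counts particular to these lists, because each score is a mean of genes on the same arrays and carries whatever varies across them. Among 100 lists, the real one and random ones of the same size and mean level, 53, 29 and 41 gave at least as many genes as the neuroendocrine, mitosis and androgen-responsive lists, with medians of 23, 3759 and 1930 over the random ones and highest counts of 4705, 7790 and 7233. Covariation that any list of genes carries can thus account for the size of each count. The neuroendocrine count was moreover 0 without P235, P803 or P1469.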
